A study of Mus musculus with 86 samples.

How the data were processed

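RNA was measured in 86 single cells of wild-type mouse kidneys at 12.5 days post coitum (Theiler stage 20). Per the labels' protocols, kidneys were pooled, dissociated with trypsin and loaded on a Fluidigm C1 instrument, which isolates each cell in its own chamber. The chambers were inspected by microscope before lysis, and full-length cDNA libraries were sequenced on an Illumina HiSeq2500. All cells come from 1 pool, so they are 1 sample and not replicates of each other. No test was made, and no p-value or standard error is given.

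The deposited RPKM values (reads scaled to gene length and to the mapped reads of each cell) were used on the linear scale, as the authors made them. A first table holds 12360 genes in 86 cells, and it lists only genes that the authors counted above an RPKM of 3 in at least 3 cells, per the file headers. A second table holds 450 genes in 35 of these cells, with RPKM values that are not the same as those of the first table. It also holds the authors' fold of cells they call six2only over cells they call six2andcited1, per the file headers. Which of the 35 cells belongs to which of these classes is not named in the columns, so no class was assigned. TopHat 1.4.1, DESeq and the genome build mm9 are listed per the submitters' processing notes, with no role or order given. Coordinates are those of the authors' tables. Read totals behind the RPKM values are unknown, so no detection limit is given.

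A gene was called detected in a cell at an RPKM of at least 1. Genes detected per cell had a median of 6164 and a range from 3458 to 7100. No doublet caller was run. No cell lay more than 2 median absolute deviations above the median number of genes, and 5 cells lay more than 3 below it. All of them were kept.

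The clustering, the gene lists, the way of comparing groups and the rule for naming genes were chosen before the data were examined. Which groups to compare was settled only once they were known. Genes detected in at least 3 cells were taken as log2(RPKM + 1), with every gene of the fixed lists left out. The rest were split at random into equal parts, and the 2000 most variable genes of one part were reduced to 10 principal components. Ward linkage then gave between 4 and 10 clusters, by the highest mean silhouette. This gave 6 clusters with a silhouette of 0.147. None of them met the marker rule for a cell type name.

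A further grouping was chosen after seeing the data. The cells were clustered by Ward linkage on 55 marker genes of 4 lists: nephron progenitor, induced nephron, stroma and ureteric bud. Values were log2(RPKM + 1), centred per gene. Between 2 and 8 clusters were tried, on values as they were and on values divided by their SD. A version with 4 clusters, which parted 14 induced-like cells from 40 others, was looked at first. The version with 3 clusters was taken, because its silhouette of 0.202 was the highest (0.173 with 4 clusters). With a pseudocount of 0.1, 10 of those 14 cells stayed together, in a cluster of 27 cells that was not induced-like, and 3 fell in the induced-like one. With scaled values the silhouette was highest for 2 clusters, at 0.398, against 0.150 for 3. The 55 marker genes define these groups and are not counted as results of them.

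A ratio between groups is the log2 ratio of (mean RPKM + 1). Genes were named by a fixed rule among genes outside the clustering. They had a mean RPKM of at least 10 in the higher group and were detected in at least 50% of its cells. The 10 highest and 10 lowest ratios were named, together with up to 4 members of each of 23 fixed lists, the 2 highest and the 2 lowest with a mean RPKM of at least 1 in either group. Six2, Cited1, Wnt4, Lhx1, Pax8, Foxd1, Meis1, Ret and Gata3 were always named where they took no part in the clustering. A list is given by the median ratio of its members outside the clustering, and by the number of 10000 random lists of the same size and matched on mean expression that lay below it. This is a description of these cells. Shares of cells have exact Clopper-Pearson 95% intervals, which cover counting error only. No ratio is given against a group in which a gene is listed at 0.

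Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9. The calculations were tested on simulated data, in which each of the 12360 genes was shuffled over the cells on its own. Then 200 genes were raised by known folds, drawn from genes with a mean RPKM of at least 10 that were detected in at least 50% of cells. The shuffling removes the depth of cells and the links between genes, so the test does not cover these or genes found in few cells. For nephron progenitor-like over stroma-marker cells, 50 genes raised by a log2 fold of 3 were found at a median of 3.00, and 98.0% of 50 genes raised by a log2 fold of 1 were found higher. For 7 against 79 cells, 92.0% of 50 genes raised by a log2 fold of 1 were found higher.

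The alternatives tried were other detection limits, a pseudocount of 0.1, the mean of log2 values in place of the log2 of means, a common total per cell, cells of few genes or small clusters left out, other clusterings, and list members limited by expression. The closing section gives their effect.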

Results

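The data describe single cells of the mouse metanephros at 12.5 days post coitum, when nephron progenitors (cap mesenchyme), stroma and the branching ureteric bud lie side by side. The labels give no cell type, and the stated aim is a transcriptional atlas of the developing kidney at single-cell resolution. Expression was measured as RPKM in 86 cells of 1 pool, so values are described over cells and no difference was tested. Each cell had a median of 6164 detected genes (range 3458 to 7100, SD 796). The sum of RPKM per cell had a median of 439945 (range 404658 to 503816), and the number of reads behind these values is unknown.

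Six2, Foxd1 and Meis1 were each detected in most cells, and Ret in few. Six2, a nephron progenitor gene on chromosome 17 (86083608 to 86087594, mm9, gene 20472), was detected in 49 of 86 cells (57.0%, interval 45.8 to 67.6%). Cited1 was detected in 35 cells (40.7%, 30.2 to 51.8%). Foxd1, a stroma gene on chromosome 13 (99124200 to 99126660, gene 15229), was detected in 59 cells (68.6%, 57.7 to 78.2%), and Meis1 in 83 cells (96.5%, 90.1 to 99.3%). Pax8 was detected in 28 cells, Lhx1 in 13 and Wnt4 in 11. Ret was detected in 6 cells (6.98%, 2.60 to 14.6%).

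Clustering without the marker genes gave 6 clusters. Cluster 5 held 34 cells (39.5%, 29.2 to 50.7%) and cluster 6 held 29 cells (33.7%, 23.9 to 44.7%). Cluster 2 held 13 cells, clusters 1 and 4 held 4 cells each, and cluster 3 held 2 cells. These clusters carry numbers and no cell type name. With variable genes from the other random part of the genes, 10 clusters arose, the largest with 23 cells, and the adjusted Rand index against the first clustering was 0.291. Without the 5 cells of few genes, 7 clusters arose and the index was 0.324. With the list genes included it was 0.515, with a pseudocount of 0.1 0.638 and with k-means clustering 0.778. With 1 cluster more it was 0.853 and with 1 fewer 0.995. Membership of these clusters thus depends on the choices made.

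Clustering on the 55 lineage markers, chosen after seeing the data, gave 3 groups. The nephron progenitor-like group held 54 cells (62.8%, 51.7 to 73.0%). It is mixed: Six2 was detected in 44 of these cells, Pax8 in 24 and Wnt4 in 10. Some of its cells carry more induced nephron than progenitor markers, such as cell 5 with 11 against 5. Others carry more stroma than progenitor markers, such as cell 73 with 11 against 5 and cell 60 with 13 against 8. A stroma-marker cluster held 25 cells (29.1%, 19.8 to 39.9%). It is not named by a cell type, because its leading genes held Rgs5, a gene of mural cells, and no stroma marker. The ureteric bud-like group held 7 cells (8.14%, 3.34 to 16.1%). The 25 cells of the stroma-marker cluster fell into clusters 1, 2, 3 and 5, with 16 of them in cluster 5. The nephron progenitor-like cells fell into cluster 5 (18 cells), cluster 6 (24 cells), cluster 2 (8 cells) and cluster 4 (4 cells). Of the 7 ureteric bud-like cells, 5 were in cluster 6 and 2 in cluster 2.

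**Figure D1:**
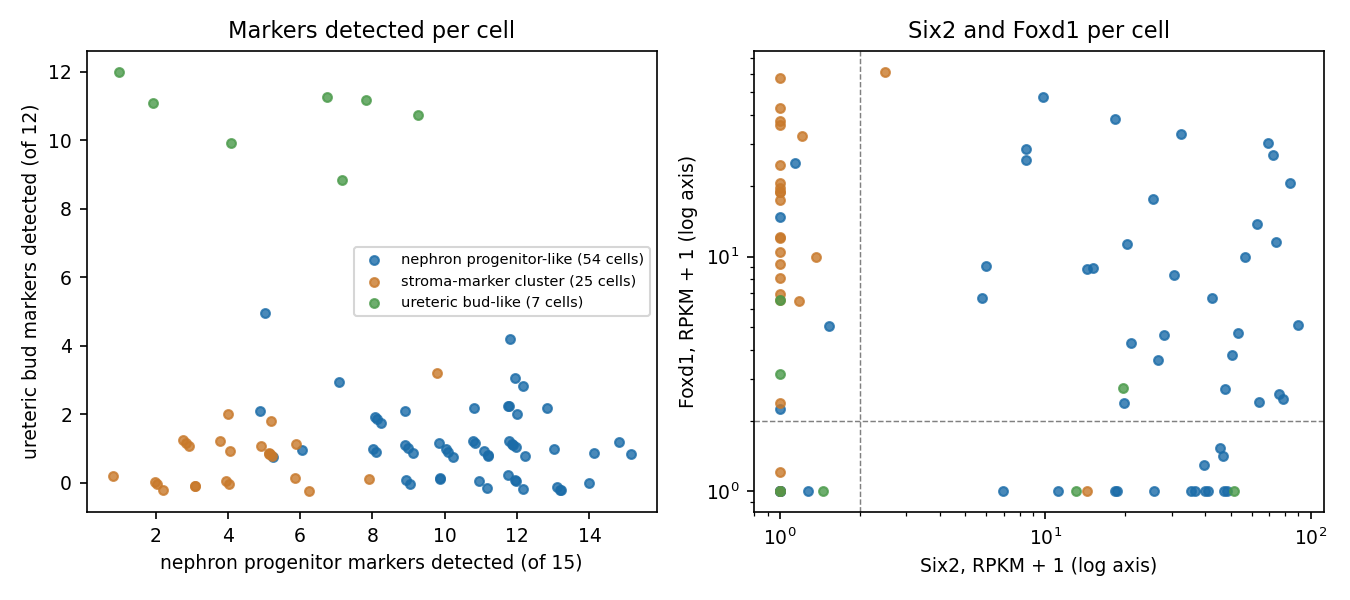
Left, number of nephron progenitor markers (of 15) and ureteric bud markers (of 12) detected in each of 86 cells, with points spread slightly to separate ties; right, RPKM + 1 of Six2 and Foxd1 in the same cells on log axes, with dashed lines at an RPKM of 1. The 7 ureteric bud-like cells detect between 9 and 12 bud markers, and 32 cells lie above both dashed lines.

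Clusters 5 and 6, found without any listed gene, differed in lineage genes. Stroma, mural and matrix genes were higher in cluster 5. Epithelial, ureteric bud and induced nephron genes were higher in cluster 6. Nephron progenitor genes were only slightly higher in cluster 6. Some lists share genes and are not separate evidence. Col1a1, Col1a2, Col3a1, Dcn, Lum and Postn are in both the stroma and the matrix list. Cdh1, Epcam, Krt8 and Krt18 are in both the ureteric bud and the epithelial list.

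All 17 stroma markers were lower in cluster 6 than in cluster 5, with a median log2 ratio of -2.71, below all of 10000 random lists. Foxd1 had a mean RPKM of 2.58 (SD 5.85) in cluster 6 and 17.4 (SD 15.4) in cluster 5, a log2 ratio of -2.36. Meis1 had a log2 ratio of -1.63, with 56.1 against 176. Col3a1 was detected in 2 of 29 cells of cluster 6 and in 31 of 34 cells of cluster 5, with a log2 ratio of -4.07. Col1a2 had a log2 ratio of -3.75. Meis2 (-0.83) and Tcf21 (-1.09) differed least among the stroma markers. The mural list had a median of -2.36 over 5 members, led by Rgs5 at -5.21, with a mean RPKM of 2.55 (SD 11.1) against 131 (SD 241). Other mural genes were in few cells, such as Tagln, in 0 of 29 and 5 of 34. Of 19 matrix genes 17 were lower in cluster 6, with a median of -1.84. The exceptions were the basement membrane collagens Col4a1 (1.33) and Col4a2 (0.84). Vcam1 (-4.62), 6230427J02Rik (-4.61), S1pr3 (-4.43), Cald1 (-3.84), Ebf1 (-3.74), Pla2g4a (-3.61) and Nfia (-3.49) completed the lowest genes. With the mean of log2 values Rgs5 was at -3.75 and Vcam1 at -2.71. Nfia was detected in all 34 cells of cluster 5 and in 6 of 29 cells of cluster 6.

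The 12 ureteric bud markers were all higher in cluster 6 (median 2.74), as were all 15 epithelial genes (median 2.68). Calb1 was detected in 6 of 29 cells of cluster 6 and in 1 of 34 cells of cluster 5, so a few cells carry this ratio, and 5 of the 7 ureteric bud-like cells are in cluster 6. With the mean of log2 values, the medians of these lists were 0.63 and 0.62, that of the induced nephron list 0.62, mural -0.57, matrix -1.10 and stroma -1.80, and 8 of the 20 highest and lowest genes were named again. Wfdc2 was more widely detected, in 23 of 29 against 14 of 34 cells, with a mean RPKM of 186 against 10.4 and a log2 ratio of 4.04. Of 11 induced nephron genes 10 were higher in cluster 6 (median 1.65). Pax8 had a mean RPKM of 61.5 (SD 100) in cluster 6 and 5.93 (SD 19.9) in cluster 5, a log2 ratio of 3.17. Lhx1 had a log2 ratio of 2.32 and Wnt4 of 1.46, each detected in 8 of 29 cells, and of 0.87 and 0.93 with the mean of log2 values, which gave Pax8 2.50. The Notch list had a median of 0.57. Its target Hey1 was higher in cluster 6 (2.23), as was the ligand Dll1 (2.63), detected in 5 of 29 cells, while Heyl was lower (-0.48). Bmp7 had a log2 ratio of 2.52, and Bmp4 went the other way at -1.40. Pdgfa (2.87), X99384 (2.33), Pcgf6 (2.20), Tom1l1 (2.07) and Lamc1 (2.02) completed the highest genes.

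The 15 nephron progenitor genes had a median of 0.54, with 13 higher in cluster 6 and 9997 of 10000 random lists below. Cited1 had a log2 ratio of 2.58 and Six2 of 1.24, with a mean RPKM of 30.7 (SD 26.2) against 12.4 (SD 20.0). Crym had 525 against 138, a log2 ratio of 1.92. Gdnf (-0.34) and Meox1 (-0.10) were slightly lower. All 14 glycolysis genes were higher in cluster 6 (median 0.45), with Hk2 at 0.91 and Gpi1 at 0.82.

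The comparison of nephron progenitor-like cells with the stroma-marker cluster asks what else parts the cells with these markers. Genes outside the 55 markers included a claudin, an enolase and some homeobox genes on the progenitor side. The 10 posterior Hox genes as a list went both ways, with 6 higher and 4 lower. Mural and matrix genes lay on the other side. The highest and lowest genes depend on the way of averaging: with the mean of log2 values only 6 of these 20 genes were named again, without the 5 cells of few genes 13, with groups from scaled markers 14, and without clusters 1, 3 and 4, which detect few genes, 11.

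Cldn9 was detected in 44 of 54 nephron progenitor-like cells and in 0 of 25 cells of the stroma-marker cluster. Its mean RPKM was 87.6 (SD 89.9) against 0.0970, a log2 ratio of 6.33, which was 4.92 with the mean of log2 values and 2.86 with groups from scaled markers. Eno3 was detected in 51 of 54 against 7 of 25 cells, with 157 (SD 131) against 3.63 (SD 13.3) and a log2 ratio of 5.09 (4.02 with groups from scaled markers). Fam132a had a log2 ratio of 3.92, Phf19 of 3.81, Meox2 of 3.71, Spint2 of 3.59 and Crip2 of 3.21, and with the mean of log2 values these were 2.63, 2.12, 3.15, 1.89 and 2.40. Tpbg (2.95) was detected in 51 of 54 against 5 of 25 cells. Tmem68 had a log2 ratio of 2.98 (1.65 with groups from scaled markers). Among homeobox genes, Hoxb9 had a log2 ratio of 3.15 (1.74 with the mean of log2 values) and Hoxd12 of 3.25. Hoxd11 was higher at 1.23, while Hoxc11 (-1.11) and Hoxd9 (-1.04, though detected in 23 of 54 against 8 of 25 cells) were lower, and the posterior Hox list had a median of 0.17.

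Rgs5 had a log2 ratio of -3.10, with a mean RPKM of 21.0 (SD 46.1) in nephron progenitor-like cells and 188 (SD 293) in the stroma-marker cluster. Ifitm3 (-2.92), Sparcl1 (-2.84), Rnase4 (-2.74), Fhl2 (-2.72), Gpm6b (-2.71), Ebf2 (-2.63), AW551984 (-2.60), Asb4 (-2.56) and Pmp22 (-2.53) followed. Without clusters 1, 3 and 4, which detect few genes, Sparcl1 (-1.86), Rnase4 (-1.52), Gpm6b (-1.90), Ebf2 (-1.69), AW551984 (-1.60) and Pmp22 (-1.46) stood closer to 0. Fhl2 was detected in 20 of 25 cells of the stroma-marker cluster and in 13 of 54 nephron progenitor-like cells. All 5 mural genes were lower in nephron progenitor-like cells, with a median of -1.62. Of 13 matrix genes outside the clustering 9 were lower, with a median of -1.24, and the median was -0.60 without the cells of few genes and -0.71 without clusters 1, 3 and 4. With the mean of log2 values the medians were -0.62 for mural and -0.57 for matrix genes. Col4a1 (1.18) and Col4a2 (0.99) were again higher. Bmp7 had a log2 ratio of 1.99. Bmp4 had a lower mean, 4.94 (SD 12.7) against 22.7 (SD 53.1), but was detected in 16 of 54 against 5 of 25 cells, so few cells carry its mean in the stroma-marker cluster. Spry4 was lower in nephron progenitor-like cells at -1.63.

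All 17 G2/M genes were higher in nephron progenitor-like cells, with a median of 0.59, above all of 10000 random lists, and of 1.29 with the mean of log2 values. Libraries of few genes move with this list: clusters 1 and 3, with medians of 3836.5 and 4783.5 detected genes, lie wholly in the stroma-marker cluster, and 0 of 4 and 0 of 2 of their cells detect at least 50% of the list. Without the cells of clusters 1, 3 and 4 the median was 0.43 with 16 genes higher, and without clusters 1 and 3 alone 0.34 with 13 higher and 9966 of the random lists below, both chosen after seeing the data. Cdc20 (1.77) and Plk1 (1.33) differed most. The S phase list had a median of 0.15. Among glycolysis genes 12 of 14 were higher, with a median of 0.34, and Eno1 had a log2 ratio of 0.76.

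The ureteric bud-like cells stood apart by epithelial genes. The 7 cells were set against the other 79. Mal2 and 5 claudins were among the 10 highest genes, and Sepp1 was the lowest. With the mean of log2 values 11 of the 20 highest and lowest genes were named again.

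Mal2 had a mean RPKM of 1781 (SD 473) in all 7 cells and 0.395 (SD 0.516) in the other cells, a log2 ratio of 10.32. Mia1 (7.06) and Wfdc15b (6.88) were each detected in all 7 cells and in 1 of 79 others. Cldn6 (6.67), Cldn4 (6.58), Cldn3 (6.57), Cldn8 (6.32) and Cldn7 (6.02) followed, with Ap1m2 (6.42) and Rab25 (6.26). Their order depends on the averaging: with the mean of log2 values Cldn6 was at 7.80, Cldn8 at 5.57, Ap1m2 at 5.38, Cldn4 at 4.68 and Rab25 at 4.68. With a pseudocount of 0.1 Rab25 was at 9.51 and Cldn6 at 7.23. Cldn8 was detected in 7 of 7 and in 0 of 79 cells. The epithelial list had a median of 3.10 over 11 members, of which 9 were higher, above all of 10000 random lists. Cdh6 (-1.05, detected in 1 of 7 and 9 of 79 cells) and Pard3 (-0.89) were lower. A pseudocount of 0.1 moved the median to 6.03.

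Sepp1 had a log2 ratio of -5.60, with a mean RPKM of 0.556 (SD 1.35) against 74.2 (SD 107). Emp3 (-4.48), Pcolce (-4.36), Hexa (-4.35), Pias3 (-4.01), Snai2 (-3.88), Adamts1 (-3.78), Epb4.1l2 (-3.71) and Hist1h4i (-3.67) were also low. With the mean of log2 values Sepp1 was at -3.75, Emp3 at -3.38 and Pcolce at -2.22. Renbp was listed at 0 in all 7 cells and detected in 40 of 79 others. All 10 posterior Hox genes were lower, with a median of -1.05 and 110 of 10000 random lists below, and Hoxd10 (-2.35) and Hoxc10 (-1.89) differed most. Negative medians were common among random lists in this comparison: the Notch list, at -0.44, had 4018 of 10000 below it. Of 8 BMP pathway genes 7 were lower (median -1.06, and -0.54 with groups from scaled markers), with Bmper at -2.67 and Id1 at -1.99, while Bmp7 was higher at 1.90. In the FGF list (median 0.65), Etv5 (2.10) and Dusp6 (1.83) were higher and Fgfr2 (-1.37) was lower, though detected in 6 of 7 and 60 of 79 cells. The Wnt response list had a median of 0.87, with 4 of 6 members higher, and of 1.55 over members with a mean RPKM of at least 1. The glycolysis list had a median of 0.62. The immediate early list had a median of -0.91, with Fos at -2.31. Of 10000 random lists, 195 lay below the immediate early list and 47 below the BMP list. For the FGF list 9979 lay below, for the Wnt response list 9872 and for the glycolysis list 10000.

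**Figure D2:**
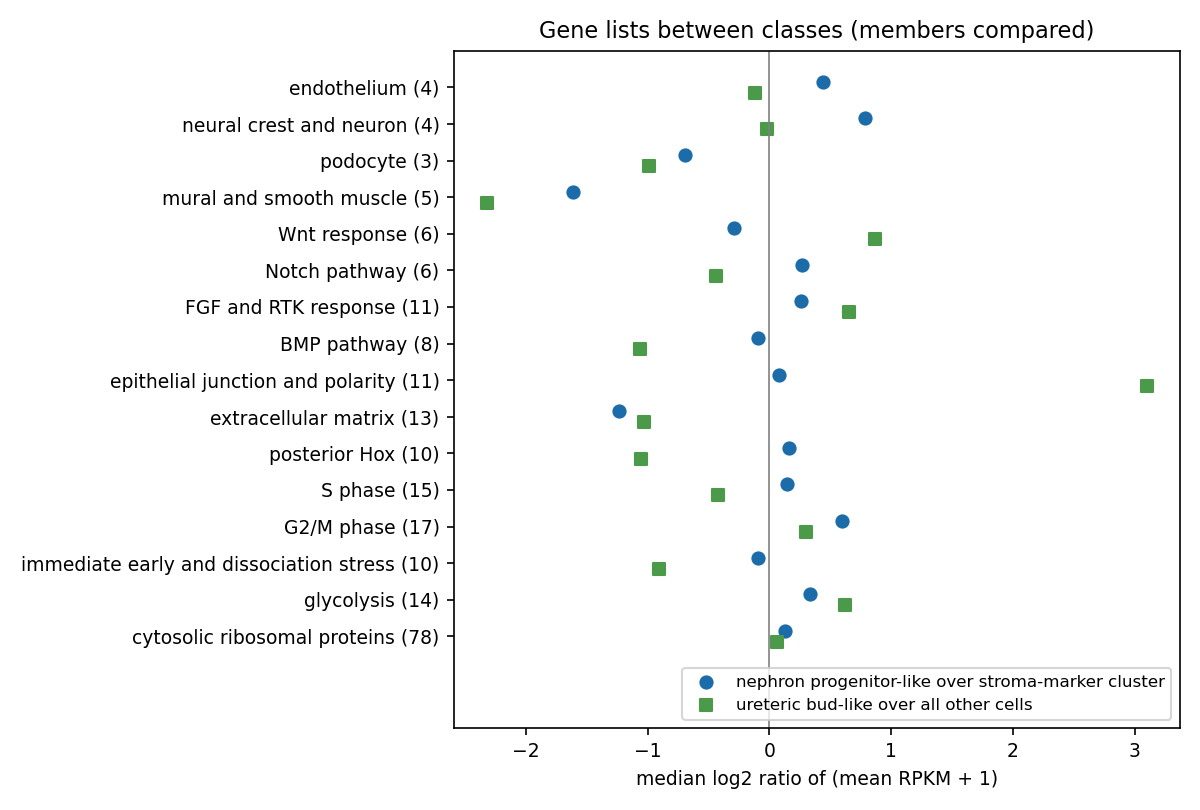
Median log2 ratio of (mean RPKM + 1) over the members of each fixed list that took no part in the marker clustering, for nephron progenitor-like cells over the stroma-marker cluster (circles) and ureteric bud-like cells over all other cells (squares). The epithelial list stands at 3.10 in ureteric bud-like cells, and the mural list is negative in both comparisons.

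The authors' second table addresses induced against uninduced progenitors, as cells with Six2 alone and cells with Six2 and Cited1. It lists genes chosen by the authors, so it is described as deposited. The progenitor genes in it were mostly lower in the cells with Six2 alone. No gene of the induced nephron list is in it, where its size alone would give 0.400.

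The authors' deposited table holds 267 genes higher and 183 lower in cells with Six2 alone, none with a fold below 2.02 in size. The median fold was 4.10 among higher genes and -4.07 among lower genes in the authors' deposited table. The authors' deposited table gives Cited1, which defines the classes, a fold of -74.7. In the authors' deposited table, 6 nephron progenitor genes appear, Cited1 included, where 0.546 would by the size of the list alone. That number takes every gene of the first table as equally likely to be listed, which genes expressed in cells with Six2 may not be. Of these 6, 5 were lower in the authors' deposited table: Cited1, whose direction the classes fix, Osr1 (-17.3), Meox1 (-4.28), Spock2 (-3.85) and Crym (-2.16). Tmem100 was higher, with a fold of 14.2 in the authors' deposited table. Other lower genes in the authors' deposited table were Ctsz (-17.3), Coq9 (-12.2), Gprasp1 (-10.0), Gm16515 (-9.91) and Arf2 (-9.32). Other higher genes in the authors' deposited table were 2310046O06Rik (14.7), G6pc3 (11.1), Peo1 (10.8), Ablim1 (10.6) and Tagln2 (10.3). Aldh1a2 (6.35), Bmper (6.42) and Znrf3 (5.06) were higher and Col4a2 (-6.10), Ramp2 (-5.43) and Elavl4 (-4.21) lower in the authors' deposited table. None of the 17 G2/M genes is in the authors' deposited table, where 0.619 would be by size alone. The S phase gene Mcm6 is lower in the authors' deposited table (-2.30). All 35 cells of this table detected Six2 in the first table, with a lowest RPKM of 7.45, and 22 of them detected Cited1. A further 10 cells had a Six2 RPKM at or above 7.45. By markers, 32 of the 35 cells were nephron progenitor-like, 2 ureteric bud-like and 1 in the stroma-marker cluster.

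**Figure D3:**
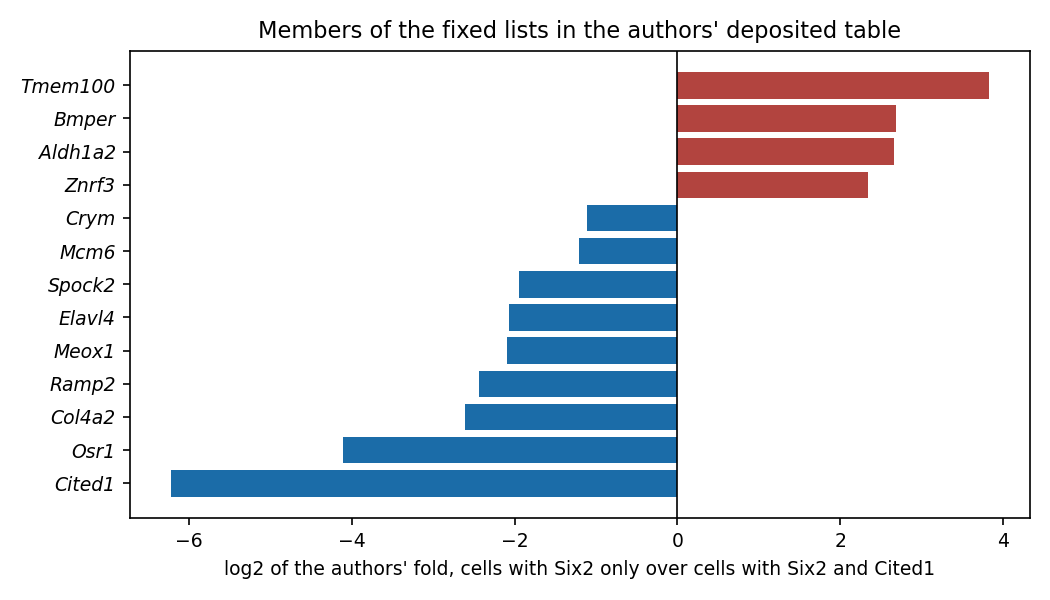
Bars give log2 of the authors' fold, with its sign, for members of the fixed lists in the authors' deposited table, in cells with Six2 only over cells with Six2 and Cited1. Cited1 has the lowest fold, -74.7, and Tmem100 the highest of these genes, 14.2.

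Pairs of lineage genes were detected together in numbers of cells near those their single frequencies give. These frequencies pool groups in which Six2 was detected in 44 of 54, 2 of 25 and 3 of 7 cells. Nearness to them thus says little about single cells. Six2 and Foxd1 were together in 32 of 86 cells (37.2%, 27.0 to 48.3%), where 33.6 would be by these frequencies alone, and 30 of these were nephron progenitor-like. Cited1 and Foxd1 were together in 26 cells (30.2%, 20.8 to 41.1%; 24.0 by frequencies alone). Every cell with Six2 also detected Meis1, in 49 cells (57.0%, 45.8 to 67.6%), against 47.3 by frequencies alone. With Meis1 in 83 cells this number could hardly differ. Six2 and Wnt4, both genes of the nephron lineage, were together in 9 cells (10.5%, 4.90 to 18.9%), against 6.27. Six2 and Ret were together in 3 cells (3.49%, 0.725 to 9.86%), against 3.42, all ureteric bud-like.

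For comparison, in the 54 nephron progenitor-like cells Ret was detected in 0, Cdh1 in 1, Krt18 in 5 and Epcam in 8. Over all 86 cells, the ureteric bud-like ones included, these were 6, 8, 13 and 15. Ret, Cdh1, Krt18 and Epcam are bud markers of the grouping, so low numbers in nephron progenitor-like cells are partly set by it. The planned background genes Cdh5, Kdr, Ptprc, Csf1r and Sox10 are not among the genes that the authors list. Only genes counted above an RPKM of 3 in at least 3 cells are listed. Their absence may thus reflect rare or low detection, and no share of cells can be given for them. In nephron progenitor-like cells, Foxd1, itself a marker of the grouping, was detected in 34 of 54 (63.0%, 48.7 to 75.7%), at a mean RPKM of 7.75 (SD 11.2). Other stroma markers were also common in these cells, with Col1a1 in 28 and Col3a1 in 26 of 54. Median genes detected were 6326 in nephron progenitor-like cells, 5946 in the stroma-marker cluster and 6488 in ureteric bud-like cells. At least 3 stroma markers were detected in all 54 nephron progenitor-like cells, and at least 3 nephron progenitor markers in 21 of 25 cells of the stroma-marker cluster. At least 3 markers of 3 lists were detected in 6 of 54 nephron progenitor-like cells, 3 of 25 cells of the stroma-marker cluster and 4 of 7 ureteric bud-like cells. A limit of these counts is the detection level: at an RPKM of at least 5, Six2 and Foxd1 were together in 19.8% of cells.

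Cell cycle genes were detected in most cells, and no difference between groups was tested. At least 50% of the 17 G2/M genes were detected in 45 of 54 nephron progenitor-like cells (83.3%, 70.7 to 92.1%). The same held for 13 of 25 cells of the stroma-marker cluster (52.0%, 31.3 to 72.2%, and 76.0% with fewer genes required or 13 of 19 without clusters 1, 3 and 4) and 6 of 7 ureteric bud-like cells (85.7%, 42.1 to 99.6%). At least 50% of the 15 S phase genes were detected in 53 of 54, 23 of 25 and 7 of 7 cells. In cluster 6 all 29 cells reached this level for G2/M genes, and in cluster 2 it was 4 of 13 (30.8%, 9.09 to 61.4%). Cluster 1 had 0 of 4 such cells and a median of 3836.5 detected genes.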

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

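Clusterings of the marker genes, the scaled markers, the fold limit of 4, leaving out clusters 1, 3 and 4 and the restriction to the authors' progenitor cells were chosen only after the results were seen. No paired analysis was possible because the cells come from 1 pool and no result comes from a test. Of 456 gene ratios under the alternatives, 327 stayed within 0.5 of the main value on the log2 scale, 126 moved further and 3 changed sign. They cover the highest and lowest genes and Six2, Cited1, Wnt4, Lhx1, Pax8, Foxd1, Meis1, Ret and Gata3, also where these define the groups. The mean of log2 values moved 59 of the ratios and a pseudocount of 0.1 moved 45, while leaving out cells of few genes moved 4. With a pseudocount of 0.1 Cldn9 was at 8.80 in nephron progenitor-like over stroma-marker cells. The mean of log2 values moved Cldn9 from 6.33 to 4.92 in nephron progenitor-like over stroma-marker cells, and groups from scaled markers moved it to 2.86. Of 324 list medians 287 stayed, 35 moved and 2 changed sign. Scaling each cell to the same total moved none of these. For the authors' folds, a pseudocount, a mean of logs, a scaling or leaving out cells could not be run, since the columns give no class per cell.

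The mean of log2 values reversed the neural list in cluster 6 over cluster 5 (-0.0096) and Pax8 in ureteric bud-like cells (0.32). Markers divided by their SD reversed Wnt4 (1.53) and Pax8 (1.23) in ureteric bud-like cells. Wnt4 and Pax8 are among the markers that define this group, so none of the counted gene ratios given as results changed sign. Leaving out clusters 1, 3 and 4 reversed the podocyte list in nephron progenitor-like over stroma-marker cells (0.12). The cause was not tested.

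The mean of log2 values kept only 8, 6 and 11 of 20 named genes in cluster 6 over cluster 5, nephron progenitor-like over stroma-marker and ureteric bud-like over other cells. In cluster 6 over cluster 5 it gave medians of 0.62 for induced nephron, -1.80 for stroma, 0.63 for ureteric bud, -0.57 for mural, 0.62 for epithelial and -1.10 for matrix genes. A pseudocount of 0.1 gave 2.38, -3.80, 4.43, -5.28, 3.68 and -2.67 for the same lists. For nephron progenitor-like over stroma-marker cells the mean of log2 values gave -0.62 for mural, -0.57 for matrix and 1.29 for G2/M genes, and a pseudocount of 0.1 gave -2.72 for mural genes. For ureteric bud-like cells it gave -3.87 for mural and 6.03 for epithelial genes, and the mean of log2 values -0.45 for mural genes. All of these kept their sign, and the cause of the moves was not tested. Without the 5 cells of few genes, 13 of 20 named genes remained in nephron progenitor-like over stroma-marker cells, the matrix median was -0.60, and the mural median of ureteric bud-like cells was -1.81. Without clusters 1, 3 and 4 these were 11, -0.71 and -1.59. With markers divided by their SD the BMP median of ureteric bud-like cells was -0.54.

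Genes detected per cell had a median of 7824 at any value above 0 and 4827 at an RPKM of at least 5, which follows from the limits. The largest planned cluster held 23 cells with features from the other part of the genes. The nephron progenitor-like group held 40 cells with 4 marker clusters and 19 with 5, which split it by construction.

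At an RPKM of at least 5, Six2 and Foxd1 were together in 19.8% of cells and Cited1 and Foxd1 in 14.0%; at any value above 0 the latter was 47.7%. Among the 35 cells of the authors' progenitor table, all of which detect Six2, Six2 was together with Foxd1 in 62.9%, with Meis1 in 100% and with Wnt4 in 22.9%, and Cited1 with Foxd1 in 45.7%. With fewer genes of a list required per cell, S phase reached 100% of nephron progenitor-like cells and G2/M 76.0% of the stroma-marker cluster. Without clusters 1, 3 and 4, S phase reached 100% of the stroma-marker cluster. With a fold of at least 4, the authors' deposited table holds 138 higher and 98 lower genes. Reads per cell are unknown, so a gene listed at 0 may be below detection: Six2 and Foxd1 were together in 46.5% of cells at any value above 0.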

Other observations

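The tests of free RNA, the lineage gene set for a second cell, the stroma genes over all cells with Six2, the removal of reads in proportion to depth and the other levels used for comparing the tables were chosen only after the results were seen. The first gene set for a second cell, the stroma genes in cells with Foxd1, and the test of effects per gene were written down before.

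Col4a1 and Bmp7 were higher in nephron progenitor-like than in stroma-marker cells (log2 ratios of 1.18 and 1.99), while Col6a1 (-2.15) and the mean of Bmp4 (4.94 against 22.7) went the other way, each carried by 5 of 25 stroma-marker cells. In ureteric bud-like cells Col4a1 (1.01) and Bmp7 (1.90) were also higher than in the other cells, and Col4a2 was lower (-0.61). No explanation was tested for these.

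Six2 was detected in 3 of the 7 ureteric bud-like cells, at an RPKM of 18.6 in cell 18, 50.4 in cell 57 and 12.1 in cell 47, and cells 57 and 47 are in the authors' progenitor table. Each of the 3 cells detected 11 of 12 bud markers and 7, 8 and 9 of 15 nephron progenitor markers, against a median of 11 in nephron progenitor-like and 4 in stroma-marker cells and 2, 1, 4 and 7 in the 4 bud-like cells without Six2, and Cited1 was below an RPKM of 1 in all 7. A second cell in the chamber is one candidate explanation: all 3 detected 100% of a first set of 4 progenitor genes, past the bound of 75.0% set beforehand, but stroma-marker cells also detected a median of 75.0%, so that set does not mark the lineage. Of 4 sets tried afterwards none parted these cells: for 11 lineage genes the lowest of the 3 cells reached 45.5%, past the bound of 36.4%, but bud-like cells without Six2 reached up to 65.6%, while the lowest cell fell short of the bound for 64 broad genes (45.3% against 48.4%) and 19 loosely chosen ones (15.8% against 26.3%), and 3 strict genes gave a bound of 0. A second cell and Six2 expression in the bud-like cell cannot be told apart here, because the sets went both ways and only 4 cells without Six2 serve as the comparison.

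Foxd1 was detected in 30 of 44 nephron progenitor-like cells with Six2 (68.2%, against 68.6% of all cells), and stromal RNA or cells, or free RNA, may be its source. In the 30 cells 24 abundant stroma genes stood at a lower quartile of 0.262 of the stroma-marker level and Foxd1 at 0.691, which met the bound set beforehand against stromal RNA (below 50% of the Foxd1 ratio), but that bound was judged wrong because the cells were chosen for Foxd1, which raises its ratio. Over all 44 cells the lower quartile was 0.207 and Foxd1 0.473, which met the old bound by less than the spread of the genes, and the bound was then tightened to the upper quartile (0.349), which did not meet it. Of 4 gene sets tried in turn for free RNA, the 17 stroma markers (0.0687 of the stroma-marker level in ureteric bud-like cells) and 12 bud markers (0.0477 of the mean of all cells in nephron progenitor-like cells) had built the groups, 13 matrix genes outside them decided nothing (0.209, upper quartile 0.406, against a lower quartile of 0.278 in nephron progenitor-like cells), and the 10 highest genes of ureteric bud-like cells outside them, which were named for being low elsewhere, stood in nephron progenitor-like cells at a median of 0.00453 and at most 0.105 of the mean of all cells, against 0.758 for Foxd1. Free RNA in the proportions of all cells would raise every gene alike, so even genes chosen for being low elsewhere bear on it. Their values argue against it as the source of the Foxd1 mean in nephron progenitor-like cells, and leave a smaller share open. RNA or cells mainly from stroma, a Foxd1-rich subset of it included, and expression in the progenitor cannot be told apart.

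The 2 tables give the same 35 cells other RPKM values: the second lay above the first by a median ratio of 1.22 to 1.52 per cell, and by 1.39 for genes at an RPKM of 1 to 10 against 1.11 at 100 or more. A constant factor per gene, as from another gene length, cannot alone be the source, because within genes the ratio fell with the level of the gene in the cell. Gene models or filters that add reads out of proportion to that level could also give such a fall and are not excluded. The median rank correlation within genes was -0.659 over 352 genes by the level in the first table. That level is the ratio's own denominator, which makes a negative value partly by construction, so the level in the second table, which works the other way, and the mean of both were used as well, and gave -0.625 and -0.646. Across genes within a cell the median rank correlations were -0.595, -0.540 and -0.566 for the same levels, negative in 35 of 35 cells each; genes are not independent replicates. Removal of reads in proportion to their depth, as of duplicates, is a candidate explanation that would give this, but other steps that act on abundant genes were not tested.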
